A study of Homo sapiens with 60 samples.

How the data were processed

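The samples are 60 mRNA libraries of HepG2 cells treated for 24 h with water extracts at 500, 100 or 20 µg/mL or with vehicle. Per the labels, total RNA was made into stranded libraries with the MGIEasy directional kit and read as 100 bp paired ends on an MGIseq instrument. The authors checked reads with FastQC 0.11.9, trimmed them with Trim Galore 0.6.5, aligned them to GRCh38 with STAR 2.7.3a and estimated gene levels with RSEM 1.3.3. The deposited table holds RSEM expected counts, unscaled read estimates for 60675 Ensembl genes. Of its nonzero values 24.5% are not whole numbers. The labels do not state the annotation release. The same table has 207 further columns that belong to no sample of this series, and they were not used here. Samples were joined to columns by the code that opens each title.

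The labels give the vehicle as 0.1% DMSO, while the description of the series names 2% DMSO and a wortmannin control. No sample is labelled as wortmannin, so that control was not analysed here. The series description also says that doses were lowered for extracts toxic below 500 µg/mL and that samples with too little RNA were dropped; the doses used here are those in the labels. All titles carry the same batch letter. Their number codes put the 3 vehicle libraries in a set without extracts, and the replicated extracts in 3 sets of 2. The labels do not say whether replicates were separate cultures, so p-values measure the spread between libraries, which could be technical in part.

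Symbols, gene types, transcript GC content and length came from GENCODE release 29, which may differ from the release the authors used. It lists 57055 of the 60675 genes. The other 3620 held 0.0398% of counts and stayed in the fit without a symbol. Expected counts summed to 17598646 to 30451640 per library. Counts were rounded and fitted in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. The 57 replicated libraries entered 1 quasi-likelihood model with a mean for each of 19 groups. Genes were kept by filterByExpr (16093 tested) and libraries scaled by TMM, with factors of 0.898 to 1.04. The common biological coefficient of variation was 4.86%. Standard errors were derived for each gene from its fold change and its quasi-likelihood F statistic, at n = 3 per group. A gene was called at an adjusted p (Benjamini-Hochberg, per comparison) under 0.05. Comparisons were each dose against vehicle (18), 500 against 20 µg/mL within each extract (6) and extracts of 1 set at 500 µg/mL (3). Differences of the dose effect between extracts of a set were tested as interactions in the same model.

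The groups, comparisons, gene lists, naming rule and main alternatives were fixed before the data were examined. Of 35 gene lists written then, 33 had at least 3 tested members. They were tested with camera on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, and again with the correlation estimated. A member counts as risen or fallen at the adjusted p over all genes, and beside it stands the count adjusted over the list alone. Named genes are protein coding, with a symbol of their own and a mean CPM of 5 or more. They are the 8 highest and 8 lowest called genes against vehicle, the 3 highest and 3 lowest between doses and the 5 highest and 5 lowest between extracts, with no overlap between the libraries compared. From each list that passed, its 3 called members with the smallest p may be named. For genes called in all 6 extracts the order is by the smallest absolute fold change among them; the overlap by dose was chosen after the data were seen and uses the same order. The text may name fewer where space is short, always from the top of a list. Some genes that the rule names are not reported here.

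The fit was tested on simulated data, drawn from the mean level and dispersion of each gene with known changes. For Citri Unshius Pericarpium at 500 µg/mL against vehicle, 75.4% of 65 genes changed by 1.5-fold, 82.1% of 67 changed by 2-fold and 93.8% of 65 changed by 4-fold were called, and 0.0445% of unchanged genes. Between doses these shares were 74.2, 82.1 and 90.9%, and between extracts 68.2, 73.8 and 92.4%. The simulated libraries hold no GC slope, no shift of the vehicle set and no correlation between libraries. The share of unchanged genes called may therefore be higher in the data. A DNA replication list shifted by 1.3-fold was called in each of the 3 comparisons. Of 32 unshifted lists 0 were called against vehicle, 1 between doses and 0 between extracts. Overlaps between extracts were set against 20 simulations without effects, which share the vehicle libraries as the data do, and against the product of independent lists. Correlations across genes treat genes that are not independent.

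Alternatives were size factors by the median ratio, no filter, a mean CPM of 1 or more, DESeq2 1.42.0, replicate number as a block, only the vehicle and the 3 doses of an extract or only the groups of both extracts compared, leaving out each library, and the mean of the other 5 extracts as reference. After the data were seen a GC trend was removed as well: for each library a lowess curve (span 0.3) of log2 CPM against GC, relative to the mean library, entered the model as an offset. GC was known for 15986 of the 16093 genes. This was also done without the second vehicle library, and with transcript length in place of GC. Lists of 30 blood cell genes, 10 BMP and SMAD targets, 10 IL6 and STAT3 targets and 9 glucocorticoid targets were written after the main results and before their own tests. For each 3 against 3 comparison the 10 splits of the 6 libraries were refitted on these alone, with the genes of the full fit. Bojungikgi-tang was described on 10685 genes as log2 ratios to the vehicle mean with 0.5 CPM added, and its lists against 10000 random lists of the same size. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.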

Results

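Messenger RNA was sequenced from HepG2 cells, a human liver cancer line that keeps many functions of hepatocytes, after 24 h with water extracts of plants and plant mixtures used for digestive complaints. The single plants were Citri Unshius Pericarpium (mandarin peel), Cimicifugae Rhizoma, Bupleuri Radix and Aconiti Lateralis Radix Preparata (processed aconite root). The mixtures were Yijung-tang, Banhasasim-tang and Bojungikgi-tang. The first 6 of these extracts were given at 500, 100 and 20 µg/mL with 3 libraries per dose. Bojungikgi-tang had 1 library per dose, and 3 libraries received vehicle (0.1% DMSO), which makes 60 libraries. Expected counts summed to 17598646 to 30451640 per library, with 21014795 to 22891342 in the vehicle libraries. The titles put the vehicle in a set without any extract and the extracts in pairs, so 3 kinds of comparison were made: 500 against 20 µg/mL within an extract, extracts of 1 set against each other at 500 µg/mL, and each dose against vehicle. Fold changes are given on the log2 scale with the standard error (SE), and levels as CPM, counts scaled to library size, ± SD, with n = 3 per group.

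The first question was which genes follow the dose of every extract. CYP1A1 (chromosome 15, 74719542 to 74725610), an enzyme that oxidises aromatic compounds and the best-known target of the aryl hydrocarbon receptor, rose from 20 to 500 µg/mL in all 6 replicated extracts, by 1.33 in Yijung-tang to 4.85 in Cimicifugae Rhizoma. AKR1B10, a reductase of aldehydes, rose by 0.70 to 1.74. GCLM, a subunit of the enzyme that starts glutathione synthesis, rose by 0.50 to 1.16. AKR1C1 rose by 0.43 to 0.94 and NQO1, a quinone reductase, by 0.36 to 0.94. The largest falls common to the 6 extracts were in 4 metallothionein genes on chromosome 16, whose products bind zinc: MT1F (-0.80 in Citri Unshius Pericarpium to -3.18 in Cimicifugae Rhizoma), MT1G (-0.69 to -3.62), MT1E (-0.64 to -2.42) and MT1X (-0.55 to -2.64). HPX, which codes for the haem carrier haemopexin, fell by 0.27 to 1.02. Of the 16093 genes tested, 26 rose and 14 fell in all 6 extracts. The lists of the 6 extracts, if independent, would share 6.15e-04 and 6.48e-04 genes, and 20 simulated sets without effects shared 0 and 0 at most. With no effect in any extract such an overlap of 0 was given in advance. Without the filter on low counts 9 genes fell in all 6.

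**Figure D1:**
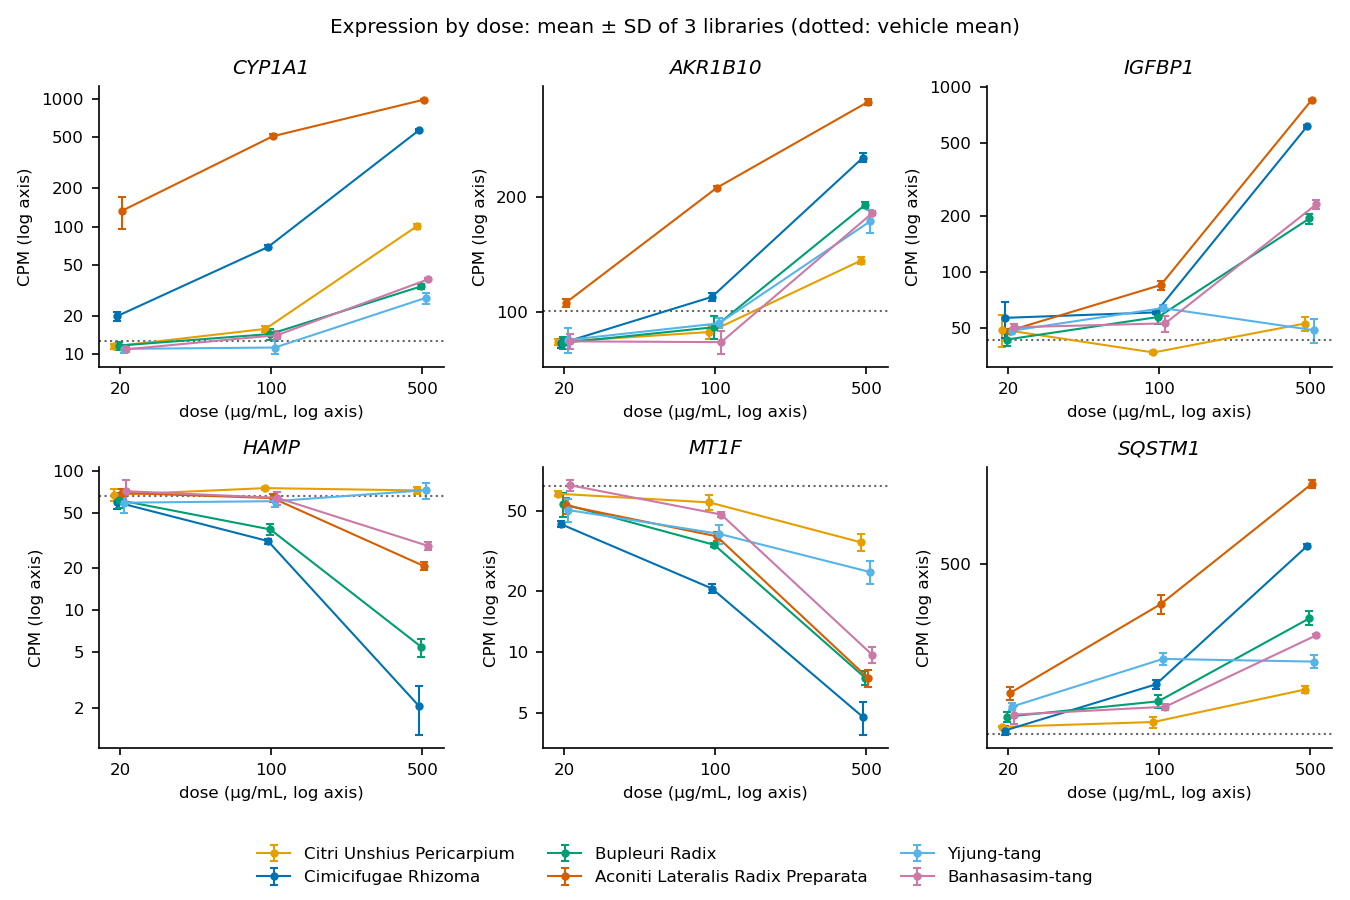
Mean CPM (log axis) of 6 genes at 20, 100 and 500 µg/mL (log axis) of each replicated extract, with bars of ± 1 SD over 3 libraries and the vehicle mean as a dotted line. CYP1A1 ends at 989 CPM in Aconiti Lateralis Radix Preparata and at 27.6 CPM in Yijung-tang, and MT1F is lowest at the top dose of each extract.

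Among the replicated extracts, Citri Unshius Pericarpium had the fewest genes called between doses in the fit as made (265, then 607 in Yijung-tang). Fits of only the libraries compared gave 172 in Citri Unshius Pericarpium and 125 in Yijung-tang. At 500 against 20 µg/mL CYP1A1 rose by 3.13 ± 0.11 (100 ± 5.01 against 11.5 ± 0.48 CPM, adjusted p = 3.53e-26), AKR1B10 by 0.70 ± 0.048 and GCLM by 0.59 ± 0.045. MT1F fell by 0.80 ± 0.090, MT1G by 0.69 ± 0.12 and EGR1, an immediate early transcription factor, by 0.70 ± 0.092. Of 23 targets of NRF2, the regulator of antioxidant enzymes, 12 rose and 11 were not called (17 rose when adjusted over the list alone, camera adjusted p = 3.61e-38). Of 9 metallothionein and zinc response genes 7 fell (8 adjusted over the list alone, adjusted p = 1.14e-16). Of 22 ATF4 and amino acid response genes 4 fell (12 adjusted over the list alone, adjusted p = 6.37e-13), with asparagine synthetase, ASNS, at -0.51 ± 0.061. Of 25 cholesterol synthesis genes 5 fell (14 adjusted over the list alone, adjusted p = 4.93e-14), among them HMGCS1 at -0.28 ± 0.057. Of 13 NF-kB and cytokine genes 4 fell (5 adjusted over the list alone, adjusted p = 6.03e-08), with complement factor B, CFB, at -0.29 ± 0.038 and the chemokine CCL20 at -0.48 ± 0.090. In all, 117 genes rose and 148 fell. This total of 265 was 174 without the third 500 µg/mL library, 163 without the second 20 µg/mL library and 421 with a GC trend removed from each library. Against vehicle the highest were CYP1A1 (2.99 ± 0.11), HES4, a repressor in the Notch pathway (1.27 ± 0.26), and the transporter SLC22A18 (1.16 ± 0.15). The lowest were MT1F (-0.93 ± 0.089), the phosphatase gene DUSP1 (-0.82 ± 0.17) and UBD (-0.75 ± 0.075). DUSP1 stood at -0.26 (adjusted p = 0.0847) without the second vehicle library.

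Cimicifugae Rhizoma gave the lowest level of hepcidin, the hormone that limits iron uptake: HAMP fell by 4.85 ± 0.19 between 20 and 500 µg/mL (59.6 ± 6.40 to 2.05 ± 0.79 CPM, adjusted p = 1.94e-26). CYP1A1 rose by 4.85 ± 0.10, to 570 ± 11 CPM, IGFBP1, which binds insulin-like growth factors, by 3.45 ± 0.098 and the water and glycerol channel AQP3 by 2.62 ± 0.073. MT1G fell by 3.62 ± 0.16 and MT1F by 3.18 ± 0.13. All 25 mitosis and proliferation genes fell (25 adjusted over the list alone, median -0.82, adjusted p = 2.83e-33), as CCNA2 (-0.96 ± 0.038), TPX2 (-0.77 ± 0.031) and KIF20A (-1.04 ± 0.043) show. Of 25 DNA replication genes 24 fell (24 adjusted over the list alone, adjusted p = 2.01e-24), the helicase subunit MCM3 by 0.81 ± 0.028. Of 11 nuclear RNAs and replication histones, listed as signs of RNA quality, 6 rose (6 adjusted over the list alone, median 0.42, adjusted p = 0.041, but 0.0643 with an estimated correlation), H2AC6 by 0.74 ± 0.098, and against vehicle 7 rose (7 adjusted over the list alone, adjusted p = 0.0171). Of 22 immediate early genes 19 rose (21 adjusted over the list alone, adjusted p = 6.40e-12), among them DUSP6 (1.19 ± 0.044), KLF6 (1.28 ± 0.060) and EGR1 (1.63 ± 0.078). Of 23 autophagy and lysosome genes 19 rose (21 adjusted over the list alone, adjusted p = 9.57e-09), with the cargo receptor SQSTM1 at 1.19 ± 0.033 and WIPI1 at 0.76 ± 0.051. Of 12 iron handling genes 7 fell and 3 rose (8 and 4 adjusted over the list alone, adjusted p = 0.0165). Besides HAMP the fall was led by ID1 (-2.32 ± 0.095) and SMAD6 (-0.99 ± 0.095), both targets of BMP signalling. Of 12 glucose response and gluconeogenesis genes 8 rose and 3 fell (8 and 3 adjusted over the list alone, adjusted p = 0.00269), with glucose-6-phosphatase, G6PC1, at 2.38 ± 0.14. Of the NRF2 targets 17 of 23 rose and 2 fell (19 and 2 adjusted over the list alone, adjusted p = 9.93e-12), and of the metallothionein and zinc genes 9 of 9 fell (9 adjusted over the list alone, adjusted p = 9.27e-12). In all 3140 genes rose and 3176 fell. Against vehicle the order was alike: CYP1A1 5.49 ± 0.11, IGFBP1 3.84 ± 0.10 and AQP3 2.77 ± 0.075 were highest, and HAMP -5.0 ± 0.19, MT1F -3.81 ± 0.12, MT1G -3.66 ± 0.16 and MT1X -2.91 ± 0.14 lowest.

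Bupleuri Radix at 500 µg/mL had more IGFBP1 than at 20 µg/mL (2.18 ± 0.097, 195 ± 12.2 against 43.1 ± 3.14 CPM, adjusted p = 3.81e-23) and more CYP1A1 (1.54 ± 0.12). HAMP fell by 3.49 ± 0.15, MT1F by 2.86 ± 0.11 and MT1G by 2.79 ± 0.14. Genes of sterol and fatty acid synthesis fell together. Of 25 cholesterol synthesis genes 22 fell (22 adjusted over the list alone, median -0.44, adjusted p = 4.30e-30), among them MVK (-0.57 ± 0.043), SQLE (-0.53 ± 0.042) and HMGCS1 (-0.68 ± 0.057). Of 15 fatty acid synthesis genes 13 fell (13 adjusted over the list alone, adjusted p = 2.68e-15), with ACSS2 at -0.68 ± 0.042 and FADS2 at -0.55 ± 0.042. Of 19 glycolysis genes 15 rose (15 adjusted over the list alone, with 1 lower, adjusted p = 3.49e-13), among them the glucose transporter SLC2A1 (0.58 ± 0.033) and ALDOA (0.42 ± 0.041). Mitosis genes fell in 23 of 25 cases (24 adjusted over the list alone, adjusted p = 1.20e-20), with CCNA2 at -0.39 ± 0.037, and DNA replication genes in 19 of 25 (20 adjusted over the list alone, adjusted p = 2.75e-13), with MCM3 at -0.34 ± 0.028. Of 22 immediate early genes 13 rose (13 adjusted over the list alone, adjusted p = 3.53e-12), IER3 by 0.96 ± 0.058 and DUSP6 by 0.64 ± 0.044. NRF2 targets rose in 16 of 23 cases and fell in 2 (16 and 2 adjusted over the list alone, adjusted p = 4.11e-11), and all 9 metallothionein and zinc genes fell (9 adjusted over the list alone, adjusted p = 8.18e-27). In all 1594 genes rose and 1430 fell. Against vehicle EIF3CL (2.55 ± 0.96), IGFBP1 (2.19 ± 0.098) and DEPP1 (1.74 ± 0.060) were highest, and HAMP (-3.59 ± 0.15), MT1F (-3.16 ± 0.11) and MT1G (-2.62 ± 0.14) lowest. EIF3CL was no longer called without vehicle replicate 1 (2.15) or 2 (2.58), or without Bupleuri Radix replicate 1 (2.20) or 3 (2.62).

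Aconiti Lateralis Radix Preparata had the highest CYP1A1 level of all groups, 989 ± 16.0 CPM at 500 µg/mL against 12.6 ± 1.49 CPM in vehicle (6.29 ± 0.11), and 132 ± 37.5 CPM already at 20 µg/mL. Between 20 and 500 µg/mL IGFBP1 rose by 4.15 ± 0.10 (adjusted p = 1.06e-34), AQP3 by 3.27 ± 0.066 and CYP1A1 by 2.91 ± 0.089. MT1F fell by 2.84 ± 0.11, MT1G by 2.60 ± 0.13 and KNG1, which codes for kininogen, by 2.16 ± 0.11. Of 22 ATF4 and amino acid response genes 19 rose (19 adjusted over the list alone, median 0.49, adjusted p = 2.61e-15), among them the cystine transporter SLC7A11 (2.15 ± 0.066), ASNS (1.46 ± 0.055) and STC2 (0.94 ± 0.045). NRF2 targets rose in 21 of 23 cases (21 adjusted over the list alone, with 1 lower, adjusted p = 3.29e-20), AKR1B10 by 1.74 ± 0.047 and GCLC by 1.20 ± 0.041. All 25 mitosis genes fell (25 adjusted over the list alone, adjusted p = 2.96e-32), KIF20A by 1.11 ± 0.042, and so did 21 of 25 DNA replication genes (21 adjusted over the list alone, adjusted p = 3.95e-15), MCM2 by 0.70 ± 0.045. Of 14 acute phase proteins 9 fell and 1 rose (9 and 1 adjusted over the list alone, adjusted p = 6.11e-07), with the fibrinogen chains FGA (-1.38 ± 0.033) and FGB (-1.03 ± 0.041) and haptoglobin, HP (-1.53 ± 0.047). Of the cholesterol synthesis genes 22 of 25 fell and 1 rose (22 and 1 adjusted over the list alone, adjusted p = 1.89e-16), with MVK at -0.83 ± 0.045. Of 19 glycolysis genes 16 rose and 1 fell (16 and 2 adjusted over the list alone, adjusted p = 1.55e-08), SLC2A1 by 1.14 ± 0.033, and of 22 immediate early genes 18 rose (19 adjusted over the list alone, adjusted p = 1.28e-14), DUSP6 by 1.35 ± 0.044. Metallothionein and zinc genes fell in 7 of 9 cases (7 adjusted over the list alone, adjusted p = 2.43e-09). The mitochondrial ribosomal RNAs MT-RNR1 (2.77 ± 0.063, 47360 against 6947 CPM) and MT-RNR2 (1.88 ± 0.066, 91620 against 24870 CPM) also rose, a pair picked out after its values were seen. From 100 to 500 µg/mL 6 small structural RNAs changed by -0.57 to 2.17. Of 11 nuclear RNAs and replication histones, listed as signs of RNA quality, 5 rose from 20 to 500 µg/mL and 0 fell (5 adjusted over the list alone, median 0.33, adjusted p = 0.181). In all 3083 genes rose and 2906 fell. Against vehicle IGFBP1 (4.32 ± 0.10) and AQP3 (3.84 ± 0.072) followed CYP1A1, and MT1F (-3.16 ± 0.11), KNG1 (-2.31 ± 0.11) and ACSM2A, of the medium-chain acyl-CoA synthetases (-2.28 ± 0.14), were lowest.

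Yijung-tang at 500 µg/mL combined higher antioxidant enzymes with lower targets of TGF-beta and YAP. Against 20 µg/mL CYP1A1 rose by 1.33 ± 0.12 (adjusted p = 1.83e-11), AKR1B10 by 1.03 ± 0.047 and the glutathione transferase GSTA2 by 0.96 ± 0.10, while MT1F fell by 1.03 ± 0.091, MT2A by 1.02 ± 0.12 and the focal adhesion protein TNS4 by 1.00 ± 0.090. NRF2 targets rose in 15 of 23 cases (19 adjusted over the list alone, median 0.30, adjusted p = 3.80e-48). Of 17 TGF-beta and YAP targets 8 fell (11 adjusted over the list alone, with 1 higher, adjusted p = 8.48e-15), among them ANKRD1 (-0.86 ± 0.056), THBS1 (-0.51 ± 0.053) and TAGLN (-0.65 ± 0.085). Of 22 immediate early genes 7 fell and 1 rose (8 and 1 adjusted over the list alone, adjusted p = 4.12e-07), KLF6 by 0.41 ± 0.062 and DUSP6 by 0.25 ± 0.045. Of 13 WNT targets 6 fell (8 adjusted over the list alone, with 1 higher, adjusted p = 2.48e-06), LGR5 by 0.36 ± 0.040, and of 13 NF-kB and cytokine genes 4 fell (6 adjusted over the list alone, adjusted p = 3.06e-07), TNFAIP3 by 0.41 ± 0.059. Metallothionein and zinc genes fell in 8 of 9 cases (8 adjusted over the list alone, with 1 higher, adjusted p = 1.19e-18). In all 266 genes rose and 341 fell. The total of 607 was 398 without the first and 374 without the second 500 µg/mL library, 343 without the first 20 µg/mL library, 292 in a fit of only its own libraries and vehicle, and 125 in a fit of only the 6 libraries compared. Against vehicle HES4 (2.05 ± 0.24), TMEM160 (1.56 ± 0.20) and GLTPD2 (1.34 ± 0.18) were highest, and MT1F (-1.42 ± 0.091), UBD (-1.06 ± 0.076) and MT2A (-1.03 ± 0.12) lowest. With the GC trend removed and without the second vehicle library, HES4 had at most 1.41 and TMEM160 at most 1.38 in any of the 6 extracts.

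Banhasasim-tang at 500 µg/mL had more IGFBP1 (2.21 ± 0.096, 233 ± 12.7 against 50.1 ± 2.03 CPM, adjusted p = 1.73e-23) and CYP1A1 (1.83 ± 0.12) than at 20 µg/mL. MT1F fell by 2.80 ± 0.10, MT1G by 2.67 ± 0.13 and MT1E by 2.04 ± 0.11. Of 20 hypoxia response genes 14 rose (15 adjusted over the list alone, median 0.42, adjusted p = 1.82e-16), among them SLC2A1 (0.46 ± 0.033) and the collagen cross-linking enzyme LOX (0.99 ± 0.077). Of 19 glycolysis genes 15 rose (15 adjusted over the list alone, adjusted p = 3.29e-21), ALDOA by 0.52 ± 0.041 and LDHA by 0.50 ± 0.043. Of 25 cholesterol synthesis genes 22 fell and 1 rose (22 and 1 adjusted over the list alone, adjusted p = 1.92e-27), MVK by 0.51 ± 0.043 and TM7SF2 by 0.49 ± 0.045, and of 15 fatty acid synthesis genes 10 fell (12 adjusted over the list alone, adjusted p = 1.48e-11), ACSS2 by 0.71 ± 0.041. Of 13 NF-kB and cytokine genes 7 rose and 1 fell (8 and 1 adjusted over the list alone, adjusted p = 9.13e-05), with CCL20 at 1.12 ± 0.079 and the adhesion molecule ICAM1 at 0.56 ± 0.042. NRF2 targets rose in 14 of 23 cases and fell in 2 (15 and 2 adjusted over the list alone, adjusted p = 1.24e-12), and all 9 metallothionein and zinc genes fell (9 adjusted over the list alone, adjusted p = 4.81e-34). In all 1383 genes rose and 1050 fell. Against vehicle IGFBP1 (2.44 ± 0.098), HES4 (1.68 ± 0.25) and TMEM160 (1.62 ± 0.20) were among the highest, and MT1F (-2.79 ± 0.10), MT1G (-2.20 ± 0.13) and MT1E (-1.80 ± 0.11) lowest. Apart from the signs of RNA quality between doses, the list calls named for the 6 extracts also held with an estimated correlation between genes.

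**Figure D2:**
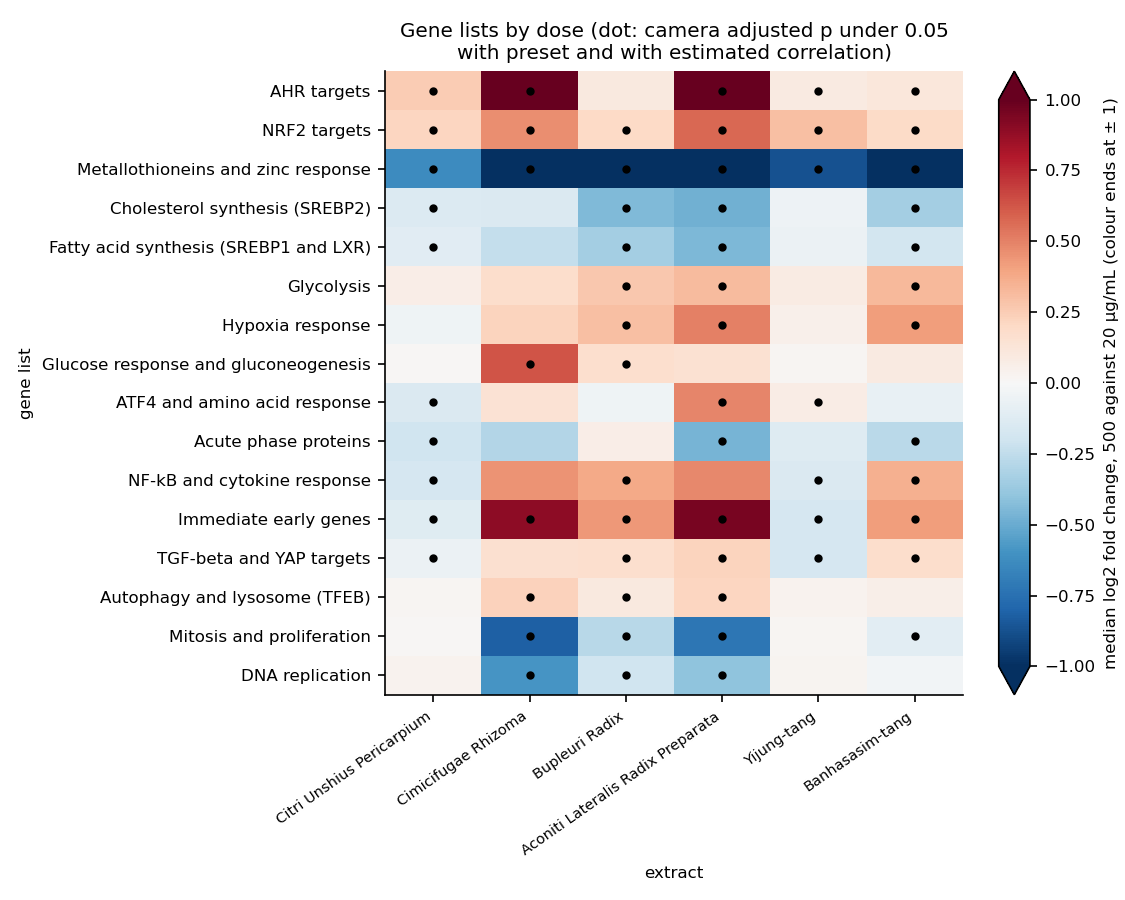
Median log2 fold change (colour) of the tested members of 16 gene lists at 500 against 20 µg/mL in each extract; a dot marks a list that passed camera with the preset and the estimated correlation. Metallothionein and zinc genes have negative medians and NRF2 targets positive medians in all 6 columns.

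The dose effects of some extracts were more alike than those of others. Across genes, which are not independent of each other, the log2 fold changes of 500 against 20 µg/mL of Cimicifugae Rhizoma correlated with those of Aconiti Lateralis Radix Preparata at r = 0.46 and with those of Bupleuri Radix at r = 0.42. Yijung-tang correlated at -0.10 with Cimicifugae Rhizoma and at -0.14 with Banhasasim-tang. With Cimicifugae Rhizoma it shared 298 genes called in opposite directions, 81 called higher in both and 67 lower in both (51.9 and 67.3 for independent lists), and with Banhasasim-tang 185, 66 and 41 (22.9 and 22.3). For the opposite calls no number for independent lists was computed. The dose changes followed GC to unlike degrees, with a Spearman correlation of 0.143 in Yijung-tang, 0.024 in Cimicifugae Rhizoma and -0.112 in Banhasasim-tang. Whether this adds to the negative correlations and opposite calls of single pairs was not tested. The mean over all pairs of extracts was 0.142, and also 0.142 with the GC trend removed, against -0.0023 in simulations without effects.

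In the set of Citri Unshius Pericarpium and Cimicifugae Rhizoma at 500 µg/mL, HAMP was higher with the former by 5.13 ± 0.18 (72.4 ± 3.69 against 2.05 ± 0.79 CPM, adjusted p = 1.34e-27). MT1G (3.34 ± 0.16), MT1F (2.88 ± 0.13), MT1X (2.59 ± 0.14) and ID1 (2.24 ± 0.095) were also higher. IGFBP1 (-3.55 ± 0.099), CYP1A1 (-2.51 ± 0.089), DEPP1 (-2.41 ± 0.059) and EGR1 (-2.12 ± 0.082) were lower. In all 3412 genes were higher and 3308 lower. In the set of Bupleuri Radix and Aconiti Lateralis Radix Preparata, the fatty acid activating enzymes ACSM3 (1.75 ± 0.045, adjusted p = 1.58e-33) and ACSM2A (1.73 ± 0.15) and the potassium channel KCNJ10 (1.68 ± 0.077) were higher with the former. CYP1A1 (-4.86 ± 0.10), AQP3 (-2.78 ± 0.064), SLC16A6 (-2.27 ± 0.065) and SOS1 (-2.16 ± 0.075) were lower, among 1802 genes higher and 1975 lower. With Yijung-tang against Banhasasim-tang, GSTA2 (1.51 ± 0.11, adjusted p = 4.58e-16), MT1G (1.43 ± 0.13), MT1F (1.37 ± 0.11) and HAMP (1.33 ± 0.11) were higher, and IGFBP1 (-2.27 ± 0.096), the chondroitin sulphotransferase CHST15 (-1.53 ± 0.11) and UBD (-1.40 ± 0.073) lower. There 1124 genes were higher and 1269 lower, and the total of 2393 was 1442 in a fit of only these 6 libraries.

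The last question was what separates all extracts from vehicle. At 500 µg/mL 797 genes were higher and 485 lower than in vehicle in all 6 extracts, against 0 and 0 in 20 simulations with shared controls and no effects. An overlap of 0 was given in advance there, as at most 2 genes per simulation were called in any extract. The simulations also hold no difference between vehicle and the other libraries, so they do not tell what the overlap reflects. Of the higher genes CYP1A1 (at least 1.13 in each extract), HES4 (1.12) and SLC22A18 (1.06) led. Of the lower genes HLA-B, an antigen-presenting molecule (-0.96), MT1F (-0.93), MT1E (-0.53) and thyroxine-binding globulin, SERPINA7 (-0.46), led. The second vehicle library held RNA of blood cell genes: 29 of 30 listed genes had 10 or more counts there, against 7 and 8 in the other vehicle libraries, and haemoglobin HBA2 had 2323 counts against 0 and 0. Without that library HLA-B was not lower in every extract (0.16 in the one that was highest), and 310 of the 485 lower and 535 of the 797 higher genes were still called in all 6. Much of that loss was not particular to it: 344 and 543 were still called without the first vehicle library, and 382 and 660 without the third. A change of sign was particular to the second. Without it the mean fold change over the 6 extracts reversed in 17 of the 485 lower genes, against 0 without the first or the third. Of the higher genes 0 reversed in each case. The vehicle libraries also differed from the others by GC content. Relative to the mean of all 60 libraries, log2 CPM changed by -0.164 to -0.139 per 10% of GC in the 3 vehicle libraries. In the other 57 it changed by -0.058 to 0.093. Those 57 make up most of that mean, which in part makes their slopes small. At 500 µg/mL the fold change against vehicle followed GC across genes (Spearman 0.274 in Cimicifugae Rhizoma to 0.559 in Yijung-tang), whereas between doses the rank correlation lay between -0.112 and 0.143. With a GC trend removed from each library 206 genes were higher and 255 lower in all 6, and without the second vehicle library as well 122 and 126. With both changes CYP1A1 had at least 0.99, HES4 0.84 and SLC22A18 0.69 in each extract, and the order of the higher genes was another.

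The number of genes called against vehicle at 500 µg/mL was 3621 in Citri Unshius Pericarpium, 7370 in Cimicifugae Rhizoma, 5739 in Bupleuri Radix, 7629 in Aconiti Lateralis Radix Preparata, 5254 in Yijung-tang and 5592 in Banhasasim-tang. With the GC trend removed and without the second vehicle library it was 1271, 6553, 3918, 6665, 1368 and 3192, in the same order of extracts. Yijung-tang fell to 3402 without its first library. At 100 µg/mL 3548 to 6041 and at 20 µg/mL 3050 to 5028 genes were called, and with both changes 379 to 3819 and 280 to 1722. In the fit as made the lowest count, 3050 in Cimicifugae Rhizoma at 20 µg/mL, became 2023 without the first vehicle library, 1810 without the second, and 1913 without its own first library.

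**Figure D3:**
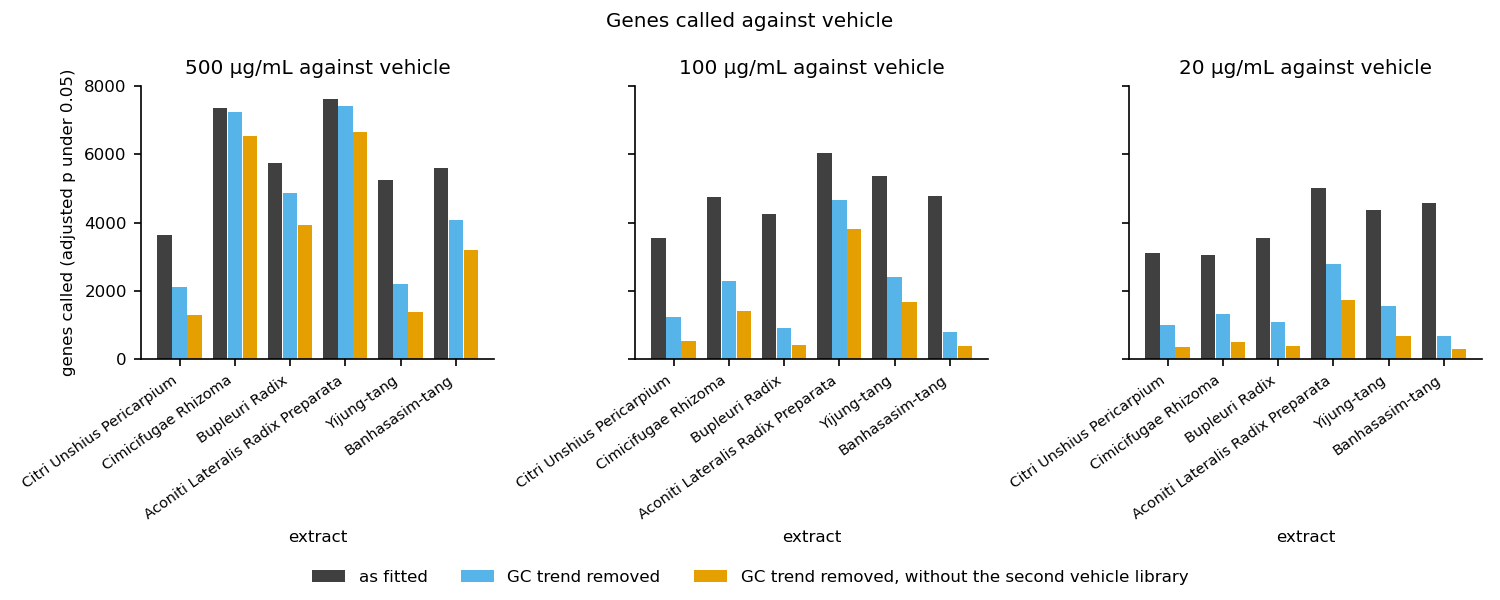
Number of genes called against vehicle (vertical axis, from 0) for each extract and dose, in the fit as made, with the GC trend removed, and with it removed and the second vehicle library left out. Aconiti Lateralis Radix Preparata at 500 µg/mL goes from 7629 to 7417 and 6665, and Banhasasim-tang at 20 µg/mL from 4576 to 660 and 280.

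**Figure D4:**
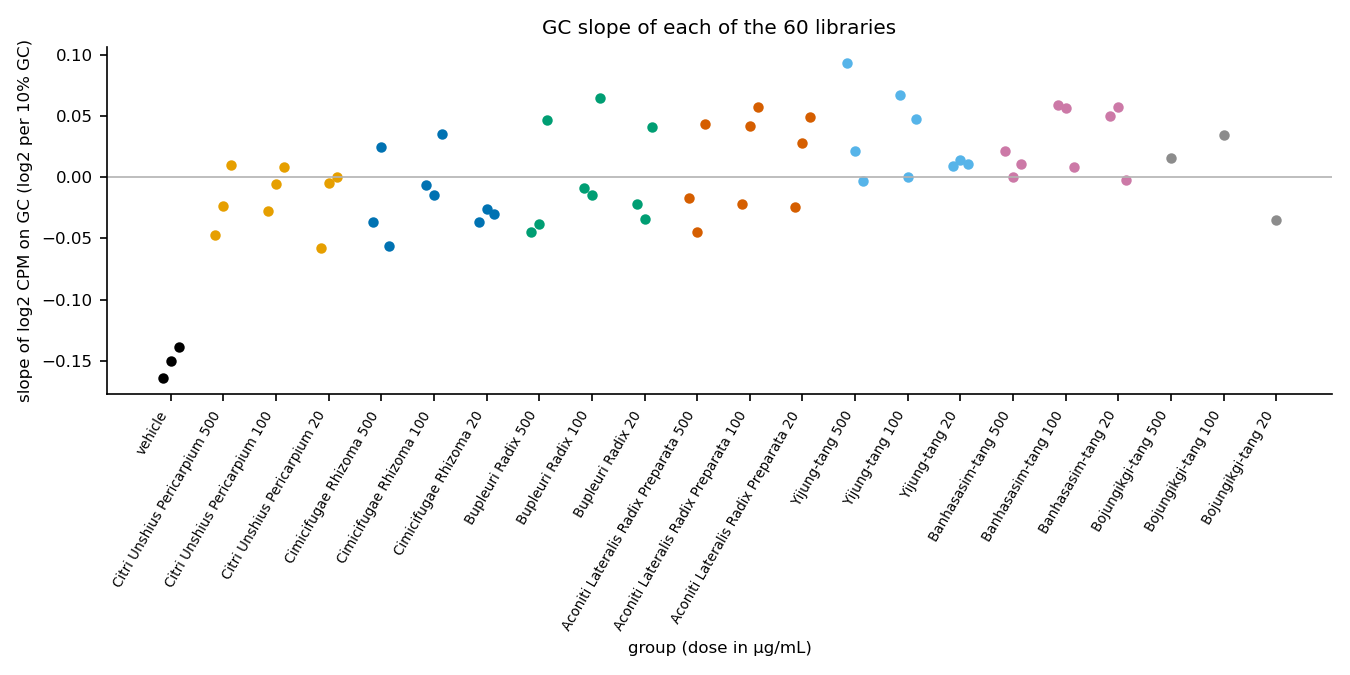
Slope of log2 CPM, relative to the mean of the 60 libraries, on GC content (log2 per 10% GC, vertical axis), with a point per library by group. The 3 vehicle points lie between -0.164 and -0.139, below all others.

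Bojungikgi-tang had no replicates, so its values carry no test. CYP1A1 stood highest against the vehicle mean at 500 µg/mL (log2 ratio 2.77, 89.4 against 12.7 CPM), with 0.88 at 100 and 0.37 at 20 µg/mL. HES4 had 1.68, 1.69 and 1.70 at the 3 doses. MT1F was lowest (-1.30), with -0.27 and -0.14 at the lower doses. As a description of these single libraries, from 20 to 500 µg/mL the medians of the AHR target list (0.41), the NRF2 list (0.21) and the mitochondrially encoded transcripts (0.25) lay above those of 10000 random lists of their size, and those of the metallothionein and zinc list (-1.02), the cholesterol synthesis list (-0.13) and the fatty acid synthesis list (-0.11) below. Of the 10685 genes with a count high enough to compare, 4035 lay above and 4340 below all 3 vehicle libraries at 500 µg/mL, 3929 and 4598 at 100 and 3684 and 3906 at 20, where chance gives 25% on each side. The vehicle libraries also differed from these 3 in GC slope (-0.164 to -0.139 against -0.0348 to 0.0346).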

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

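In this part the tests of blood RNA, of the vehicle batch, of mitochondrial RNA and of zinc were chosen only after their results were seen. Those of GC, of length, of reads shared between metallothioneins and of glucocorticoids were chosen after the main results and before their own values were seen.

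The dose effect differed between the extracts of each set by an interaction test (500 against 20 µg/mL, adjusted p under 0.05). Between Citri Unshius Pericarpium and Cimicifugae Rhizoma 4535 genes differed: the difference was 4.95 ± 0.23 for HAMP (adjusted p = 9.46e-23), 2.93 ± 0.20 for MT1G, -2.54 ± 0.089 for DEPP1 and -3.34 ± 0.14 for IGFBP1. Between Bupleuri Radix and Aconiti Lateralis Radix Preparata 1636 differed: ACSM2A by 1.60 ± 0.19 (adjusted p = 5.86e-09), ACSM3, called in opposite directions (0.60 and -0.96), by 1.56 ± 0.061, SLC16A6 by -2.09 ± 0.096 and AQP3 by -2.27 ± 0.11. Between Yijung-tang and Banhasasim-tang 1947 differed: MT1F by 1.77 ± 0.14 (adjusted p = 7.33e-14), MT1G by 1.73 ± 0.17, CHST15 by -1.74 ± 0.16 and IGFBP1 by -2.21 ± 0.14. Of these genes 52, 49 and 185 were called in opposite directions in the extracts compared.

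The first pattern is the shift of 797 genes up and 485 down in all 6 extracts against vehicle, among them higher NQO1 and lower HMGCS1. Blood-cell RNA in the second vehicle library (29 of 30 marker genes at 10 or more counts; 7 of the 30 are expressed in the other libraries) is argued against as the whole cause. Without that library the medians went from -0.32 to -0.30 and from 0.40 to 0.39, and a length trend is argued against too, since its removal left the median at 0.367 of 0.371. The higher genes had a median GC of 61.1% and the lower genes 43.4%, against 49.9% over all genes. With a GC trend removed 312 of the 1282 genes were still called in all 6 extracts and 970 were not. The median was then 0.222, above 0.5 times the 0.371 before, with a lower quartile of 0.139, below that. Part of the shift therefore goes with GC, but whether GC bias accounts for it as a whole stays open. A batch or solvent effect of the vehicle cannot be told apart from an effect of every extract, because 0 title sets hold both. At 20 µg/mL 1243 of the 1282 genes had the same sign in all 6 extracts. That comparison shares the vehicle libraries by which the genes were picked, so the agreement is partly built in. Between doses 521 were called in no extract, and 34 only the other way. The other 727, NQO1 among them, were called the same way between 500 and 20 µg/mL in at least 1 extract. No vehicle library enters there, but the 500 µg/mL libraries also served to pick the genes. Of all 16093 genes 11447 rose with dose in no extract and 11490 fell in none. These counts therefore do not decide between the 2 explanations.

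Shared vehicle libraries alone also make the extracts look alike, and part of the overlap may come from them. The mean correlation between extracts against vehicle was 0.644 against 0.507 in simulations without effects, and the mean covariance 0.181 against 0.0482. Independent lists of these sizes would share 0.731 higher and 0.326 lower genes. With the GC trend removed 206 and 255 genes were shared, while the mean correlation was 0.623.

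The second pattern is the rise of the mitochondrial ribosomal RNAs in Aconiti Lateralis Radix Preparata, MT-RNR1 by 1.98 ± 0.061 and MT-RNR2 by 1.34 ± 0.065 from 20 to 100 µg/mL, and by 0.79 ± 0.059 and 0.54 ± 0.064 from 100 to 500. A lower share of cytosolic RNA is argued against, since the 13 mitochondrial mRNAs had a median of -0.23 against vehicle at 500 µg/mL where MT-RNR2 had 2.25 ± 0.067. Carry-over of RNA without a poly(A) tail is argued against below 100 µg/mL, but only weakly. There 6 small structural RNAs such as 7SK and RN7SL1 had a median of 0.23 (0.14 to 0.58). They were scarce, at 0.65 (RPPH1) to 8.46 CPM (RN7SL2) with 20 µg/mL, and their SE ran from 0.23 (BCYRN1) to 0.52 (7SK). For single members such as 7SK (0.43 ± 0.52) a rise like that of MT-RNR2 is not excluded. Above it their median was 1.28 (-0.57 to 2.17), so that carry-over may account for the second step, and a biological rise at the first step remains a hypothesis.

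The third pattern is the fall of metallothioneins with dose in all 6 extracts. Reads shared between these genes are argued against, since their summed counts changed by -0.65 in the extract where they changed least. Lower glucocorticoid signalling is argued against: 0 of 6 extracts had a median under -0.1 over 8 tested targets (-0.044 to 0.169). Less zinc sensed by the transcription factor MTF1 may account for it, since the zinc importer SLC39A10 rose in 5 extracts (0.36 in Yijung-tang to 1.52 in Cimicifugae Rhizoma; 0.18 ± 0.073, adjusted p = 0.274, in Citri Unshius Pericarpium) and the zinc exporter SLC30A1 changed by -0.18 to -0.67 in the 6. This is a hypothesis, as zinc itself was not measured here.

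Splits of the 6 libraries of each comparison are too few for a share under 0.05, as only 1 of 10 is the real one. Fitted on the 6 libraries alone, the real splits gave 3306 (Yijung-tang) to 7636 genes at 500 µg/mL, 2838 to 6006 at 100, 2909 to 5080 at 20, 125 (Yijung-tang) to 6509 between doses and 1402 (Yijung-tang and Banhasasim-tang) to 6488 between extracts. The highest of the other splits gave 0 to 2 genes. Each of those splits has libraries of both groups in each arm, so real differences widen the spread within the arms. Few calls arise there in any case, and the values do not tell how many calls are due to chance.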

How the results depend on the processing

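The GC trend and the other settings tried on gene overlaps, on dose differences and with each vehicle library left out of the overlaps were chosen after seeing the data; the rest were planned. All 34 counts of called genes stayed within 1.5 times with size factors by the median ratio, with a mean CPM of 1 or more and with the replicate block, and all 31 with DESeq2. The rule set for pairing, that every same-numbered pair correlates over 0.1, was met in only 2 of 15 comparisons (Aconiti Lateralis Radix Preparata by dose and against Bupleuri Radix). Within title sets 61.5% of same-numbered pairs were over 0.1 and 15.2% of the others, and 70.4% of libraries were closest to their own number, a hint from the data, not the design. Same-numbered pairs had a median r of 0.15 within title sets and 0.043 over all groups. The replicate block is shared by all groups, so it cannot take up a pairing particular to a title set. That the counts held with the block does not settle whether such pairing matters. Over all settings named genes kept their direction and call in 2920 of 2939 values, 8 reversed and 11 lost the call. These genes were picked largely for strong calls, so most were likely to hold. A change in size alone was not counted. Only 56 list calls, chosen for the text, were followed through the settings. Other list calls could be lost. Against vehicle at 500 µg/mL the metallothionein and zinc list in Citri Unshius Pericarpium went from camera adjusted p = 1.71e-04 to 0.0896 with the correlation estimated. The ATF4 list in Cimicifugae Rhizoma went from 0.00905 to 0.0578 with the GC trend removed. The 56 calls that were followed held in 611 of 617 values. The 6 that did not were in Cimicifugae Rhizoma by dose: 3 lists with the correlation estimated, and the signs of RNA quality also with the GC trend removed (adjusted p = 0.0564, and 0.052 without the second vehicle library) and without replicate 1 at 500 µg/mL (0.0744).

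With the GC trend removed the counts against vehicle that moved were, at 500 µg/mL, 2098 in Citri Unshius Pericarpium and 2186 in Yijung-tang. At 100 they were 1210 in Citri Unshius Pericarpium, 2273 in Cimicifugae Rhizoma, 900 in Bupleuri Radix, 2414 in Yijung-tang and 784 in Banhasasim-tang. At 20 they were 993, 1308, 1064, 2770, 1538 and 660 in the order of the text. With the second vehicle library left out as well they were 1271, 1368 and, in Banhasasim-tang, 3192 at 500, then 528, 1409, 399, 3819, 1674 and 379 at 100, and 350, 487, 369, 1722, 654 and 280 at 20. By dose Citri Unshius Pericarpium had 421 and 427, against 265. Genes higher in all 6 extracts against vehicle numbered 206 and 122, and lower genes 255 and 126. How the GC differences between libraries arose was not tested.

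Fitted with only its own libraries and vehicle, Yijung-tang had 292 genes by dose, against 607, and fitted with only Banhasasim-tang at 500 µg/mL, 1442 between the extracts, against 2393. Without a filter 9 genes, against 14, fell with dose in all 6 extracts. The cause was not tested. With 1 library left out, where an arm of 2 is assumed to vary like the other groups, 15 of 168 counts moved by over 1.5 times. Their ranges were 3402 to 5383 for Yijung-tang at 500 µg/mL against vehicle (main count 5254), 1985 to 4484 for Bupleuri Radix at 100 (4238; the lowest without its replicate 3), 1836 to 2867 for Citri Unshius Pericarpium at 20 (3108; also 2069 and 1947 without vehicle 1 and 2, 1900 without its own replicate 3), 1810 to 2489 for Cimicifugae Rhizoma at 20 (3050), 2349 to 3263 for Bupleuri Radix at 20 (3532; the lowest without its replicate 3), 163 to 200 for Citri Unshius Pericarpium by dose (265) and 343 to 853 for Yijung-tang by dose (607). Fewer libraries leave less power, but why these libraries matter was not tested.

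With the mean of the other 5 extracts as reference 6 values against vehicle changed sign. CYP1A1 (-0.20, adjusted p = 0.0253) and MT1F (1.94, 3.14e-25) in Citri Unshius Pericarpium and MT1F (1.35, 5.74e-19) in Yijung-tang passed the test there. HES4 (-0.30, 0.2) and SLC22A18 (-0.16, 0.249) in Citri Unshius Pericarpium and IGFBP1 (-0.028, 0.903) in Bupleuri Radix did not. HLA-B in the extract nearest 0 went from -0.96 to 0.16 without the second vehicle library (-1.32 to 0.16 over the 3) and to 0.043 with the GC trend removed as well. Of 112 Bojungikgi-tang values 15 moved beyond their counting interval. DESeq2 was not run for the differences of dose effects, and a stricter filter gives no value for genes it drops. Depth limits genes near the floor of 3 counts, where a fold change rests on few reads.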

Other observations

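The tests on HAMP and on mitochondrial mRNA position in this part, and the choice of single genes against vehicle, came only after the results were seen.

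A list of drug handling genes rose with dose in 4 extracts, and its exporter ABCC2 in all 6 (0.29 to 1.20). Of 9 PXR and CAR targets, which clear foreign compounds, 6 rose and 1 fell in Cimicifugae Rhizoma at 500 against 20 µg/mL (6 and 1 adjusted over the list alone, adjusted p = 0.00121), with the bile canalicular exporter ABCC2 at 1.06 ± 0.054, the drug pump ABCB1 at 0.79 ± 0.041 and CYP3A5 at 1.23 ± 0.11. In Bupleuri Radix 4 rose and 1 fell (4 and 1 adjusted over the list alone, adjusted p = 0.00568), ABCC2 by 0.65 ± 0.053 and ABCB1 by 0.33 ± 0.041. In Citri Unshius Pericarpium 2 rose (2 adjusted over the list alone, adjusted p = 0.00161) and in Yijung-tang 2 (4 adjusted over the list alone, adjusted p = 8.61e-04), with ABCC2 at 0.36 ± 0.053 and 0.29 ± 0.053. Of 8 AHR targets 5 rose and 2 fell in Cimicifugae Rhizoma (5 and 2 adjusted over the list alone, adjusted p = 0.00961) and 6 rose in Aconiti Lateralis Radix Preparata (6 adjusted over the list alone, adjusted p = 1.48e-05). The repressor of that receptor, AHRR, rose by 2.69 ± 0.23 and 2.98 ± 0.19. With the preset correlation the AHR list also passed camera in Citri Unshius Pericarpium (adjusted p = 7.16e-11), Yijung-tang (3.74e-07) and Banhasasim-tang (0.0335). It did not pass in Bupleuri Radix (0.722). In Cimicifugae Rhizoma by dose 11 of 16 heat shock genes fell (11 adjusted over the list alone, adjusted p = 6.22e-04), HSP90AA1 by 0.43 ± 0.044 and the co-chaperone DNAJA1 by 0.35 ± 0.041. There 7 of 16 PPARA and fatty acid oxidation genes rose and 2 fell (7 and 2 adjusted over the list alone). The camera adjusted p was 0.013, and 0.0643 with an estimated correlation. CPT1A rose by 1.01 ± 0.048, the lipid droplet protein PLIN2 by 0.65 ± 0.041 and VNN1 by 2.37 ± 0.15. Of 18 unfolded protein response genes 12 fell and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 7.78e-04, and 0.0643 with an estimated correlation), the chaperone HSPA5 by 0.39 ± 0.031. In Banhasasim-tang 5 of 10 bile acid and FXR genes fell and 2 rose (5 and 3 adjusted over the list alone, adjusted p = 0.023), with the receptor itself, NR1H4, at -0.70 ± 0.054, the transporter subunit SLC51B at -0.57 ± 0.10 and the sterol hydroxylase CYP27A1 at -0.22 ± 0.047.

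Against vehicle, with the GC trend removed and the second vehicle library left out, some single genes were picked out for what they are known to do, after their values were seen, among those still called the same way in all 6 extracts at 500 µg/mL; no list was tested for this overlap. Higher were thioredoxin reductase, TXNRD1, by a mean of 0.46 over the 6 extracts (0.22 to 1.11), NQO1 by 0.47 (0.21 to 1.06), sulfiredoxin, SRXN1, by 0.49 (0.16 to 1.17), and GCLC, of glutathione synthesis, by 0.58 (0.24 to 1.32). Also higher were the exporters ABCC2, by 0.74 (0.32 to 1.40), and ABCC3, by 0.57 (0.24 to 1.20). Lower were HMGCS1, with a mean of -0.53 (-0.83 to -0.15), FDFT1, with -0.37 (-0.63 to -0.14), FDPS, with -0.34 (-0.59 to -0.14), and the apolipoprotein APOA1, with -0.52 (-0.92 to -0.30).

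The fall of hepcidin in Cimicifugae Rhizoma may go with lower BMP and SMAD signalling, the main inducer of HAMP. The 10 listed targets had a median of -1.43 at 500 against 20 µg/mL, with ID1 at -2.32 ± 0.095, ID2 at -1.51 ± 0.058, ID3 at -1.83 ± 0.088, SMAD7 at -1.35 ± 0.069 and ATOH8 at -2.32 ± 0.30, while BAMBI had 0.01 ± 0.072 and SMURF1 rose by 0.40 ± 0.052. Lower IL6 and STAT3 signalling stays open, as 8 tested targets had a median of -0.30 and went both ways: HP fell by 1.13 ± 0.046 and SERPINA3 rose by 0.56 ± 0.078. The BMP reading is a hypothesis, found and tested on the same libraries.

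In Aconiti Lateralis Radix Preparata the mitochondrial mRNAs of the heavy strand also changed unequally with dose, MT-ND4 at -0.90 ± 0.14, MT-ND4L at -0.73 ± 0.094 and MT-ND5 at 0.57 ± 0.10. Transcription that thins out with distance from the promoter was tested on the 12 mRNAs. The rank correlation of position with the change was -0.287, which leaves the question open with so few genes.

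Bojungikgi-tang, with 1 library per dose, was compared with the replicated extracts over 10685 genes. Its changes from 20 to 500 µg/mL, which use no vehicle library, correlated with those of Bupleuri Radix at 0.390, Citri Unshius Pericarpium at 0.352, Cimicifugae Rhizoma at 0.328, Banhasasim-tang at 0.324, Aconiti Lateralis Radix Preparata at 0.279 and Yijung-tang at 0.250.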
